A study of Mus musculus with 721 samples.

How the data were processed

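Single cells labelled as microglia, from the brains of 9-month-old mice, were profiled with Smart-Seq2. This plate-based method sequences full-length cDNA from sorted cells and carries no molecular identifiers. The mice carried floxed Dicer alleles (Dicer is the ribonuclease that cuts precursor microRNAs to their mature form), the tamoxifen-inducible recombinase Cx3cr1CreERT2, which acts in microglia, and the PS19 transgene, a mutant human tau that forms neuronal aggregates. Cells were sorted on CD45 and CD11b into 96-well plates, per the labels. The table holds 721 cells, 360 from female and 361 from male mice. Their titles carry the numbers 419 and 421 (female) and 426 and 431 (male), each found on 2 plates. These numbers were taken as animals, which the labels do not state outright. If they mark something else, the p-values measure only the spread between these samples. Mice with intact Dicer or without the tau transgene were not analysed here, so sex is the only comparison the labels give. All female cells came from library pool 1 and all male cells from pool 2, so sex and pool cannot be told apart.

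The values are whole-number counts per gene as deposited by the authors, with 23337 gene rows and 92 rows of ERCC spike-in RNA. Per the submitters' processing notes, Trim Galore 0.4.3, STAR 2.5.3a, Picard and HTSeq were used with genome build mm10. The annotation, the strand setting and any earlier filter on cells are not given in the sources used here. Counts of near-identical paralogs and of genes that overlap on opposite strands, such as Xist and Tsix, are therefore uncertain. The spike-ins took 0.619% of all counts and were left out of library sizes. The 45S pre-rRNA row Rn45s held 19.7% of the gene counts. No row of the mitochondrial genome was present, so a filter on mitochondrial reads could not be applied. Gene positions came from a RefSeq table of GRCm38.p6, the assembly behind mm10, with 20756 rows matched by current symbol, 2331 by a synonym and 250 unmatched.

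Cells with at least 10000 gene counts and at least 500 detected genes were kept, which left 711 cells and removed 10. No doublet caller was run, because wells were filled by sorting. No 2 cells had identical counts. Totals per animal were 59514763 and 61176732 gene counts (female 419 and 421) and 58255639 and 74547896 (male 426 and 431), with medians of 321374 to 417802 counts per cell. Intervals on shares of cells are exact 95% binomial intervals, and a count of 0 was bounded at 3 counts per group. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

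Counts were summed over the kept cells of each animal. The sums of 2 female and 2 male animals were compared with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, default expression filter, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. CPM values are TMM-scaled counts per 1e6 counts of these sums. Levels by animal in the first clustering, on plates and in the search for absent genes used library size alone. Fold changes are log2, male minus female. Each SE is the absolute log2 fold change divided by the square root of edgeR's F statistic. It is approximate, above all for genes near 0 counts in a group. Sums per plate (8 plates) were used with the animal as a block to compare plates, and with 4 animal levels to compare the animals of a sex, where plates are technical replicates. A set of 34 gene lists was fixed before the data were examined, and lists with at least 3 measured genes were tested with limma 3.58.1 camera at its preset correlation of 0.01 on voom values, with an estimated correlation and fry beside it. Named genes followed a rule fixed at the same time. It took Dicer1, the X- and Y-linked sex genes, up to 12 autosomal genes each way past the threshold (with fewer than 5 of these, the 10 autosomal genes with the smallest p and a mean log2 CPM of at least 3), the 3 members of each list with the smallest p, and the leading genes of each cluster.

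Cells were clustered with scanpy 1.11.5 (2000 variable genes without the sex-linked list genes, 20 principal components, 15 neighbours, Leiden resolution 0.5). Leading genes were the 10 with the highest fold over all other cells among genes detected in at least 25% of a cluster's cells. To compare gene lists between clusters, cells were clustered again without the 509 list genes, a choice made after the first clusters were seen. Clusters 1 to 4 of this clustering held 286, 259, 101 and 65 cells. Their sums per animal and cluster were tested with edgeR with the animal as a block. Cluster 2 has markers of another class among its leading genes. It was kept in the sex comparison and left unnamed, a choice made after its markers and before the sex comparison were seen. The comparison of cluster 3 with cluster 1 was computed but is not reported, because edgeR returned an infinite prior degree of freedom (sums of as few as 10 cells). Sums of cluster 4 held as few as 7 cells. That comparison is reported because its prior was finite (5.66). A sex-by-cluster interaction was planned for clusters 2 and 4 after the clusters were seen. It was also run for cluster 3, where edgeR called Apoe and Rn45s from sums of as few as 6 cells with an infinite prior degree of freedom. That result was left out after it was seen, and no other tool was run on it.

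List scores were means of z-scored log2(CPM + 1) on 706 cells thinned to 100000 counts, with unthinned counts as the alternative. Sites for microRNA families were searched as 7-base seed matches in the longest annotated 3' UTR of each gene, from the GENCODE annotation vM21. The mean site effect is the mean difference in log2 ratio, with a pseudocount of 1 CPM, between genes with and without a site. It was ranked among 1000 sets of shuffled sites, each found in a number of genes within 25% of that of the real site. For the comparison on detected genes, each cluster 4 cell was paired with the unused cell of another cluster from the same animal with the nearest number of detected genes. On simulated data for the sex comparison (11860 genes), edgeR recovered 0% of genes changed 2-fold, 10.2% at 4-fold, 29.2% at 8-fold and 44.7% at 16-fold. In the simulated site test on 8113 genes, a planted shift of 0.1 per family reached percentile 100, and with no shift the percentile was 93.9.

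Alternatives fixed beforehand covered normalization, DESeq2 1.42.0 and limma-voom in place of edgeR, gene and cell filters, thinning, single plates, plate sums, cluster resolution and leaving out each animal. Others were added after the data were seen: leaving out Rn45s, cluster 2 or cluster 3, keeping only cells with at least 1500 genes, leaving out plate 1 of female 421, and the settings of the comparisons between clusters.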

Results

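The data describe 711 single cells labelled as microglia, from 4 tau-transgenic mice in which Dicer was targeted in microglia. Whether all of them are microglia was not tested, and 248 (cluster 2, below) had border macrophage markers among their leading genes. The 711 cells comprise 175 and 183 of the female animals 419 and 421 and 172 and 181 of the male animals 426 and 431. The comparison in the labels asks how microglia in which Dicer was targeted differ between the sexes in this tauopathy model. Median detected genes per cell were 1801 and 1729 in the female animals and 1547 and 1739 in the male animals (exact permutation test, two-sided p = 0.667, smallest possible p = 0.333). Median counts per cell were 335928 and 350671 against 321374 and 417802 (exact permutation p = 1). Median gene counts per spike-in count were 207 and 194 in the female and 196 and 225 in the male animals (exact permutation p = 0.667).

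Dicer1, the targeted gene (chromosome 12, 104687740 to 104751968), was measured at 16.2 and 15.9 CPM in the female animals and 52.3 and 23.9 CPM in the male animals (log2 fold change 1.25, SE 0.59, n = 2 per sex, edgeR adjusted p = 0.999). It had counts in 7.43% and 8.74% of the cells of female 419 and 421, and in 6.98% of those of male 426 and 20 of 181 cells of male 431. Gene-level counts include exons outside the floxed part, so these values do not show whether the allele was recombined. Without the cells of cluster 3, described below by its genes, the Dicer1 log2 fold change was −0.13. In that cluster Dicer1 reached 102 CPM in male 426 (71 cells) and 0, 3.44 and 0 CPM in female 419, female 421 and male 431 (24, 9 and 6 cells). Only 12 of all 172 cells of male 426 had a Dicer1 count, so these values rest on few cells.

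The genes that edgeR called between the sexes were Xist and Eif2s3y, both sex-linked. Xist, the noncoding RNA of X inactivation, had 728 and 953 CPM in the female animals and 0.0593 and 0.0761 CPM in the male animals (log2 fold change −13.53, SE 0.49, edgeR adjusted p = 0.000381), or 105890 against 9 counts. Eif2s3y, a Y-linked translation factor gene, had 0 counts in both female animals and 9173 in the male animals, at least 2779-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.0405). The other Y-linked genes did not pass over all genes (edgeR adjusted p = 0.288 for Ddx3y, 0.554 for Kdm5d and 0.999 for Uty), while 4 of 4 passed when adjusted over the list alone. Kdm5d and Uty had 0 counts in the female animals and were at least 843-fold and at least 506-fold higher in the male animals. Ddx3y had 4 counts in the female and 6046 in the male animals. Tsix, which overlaps Xist on the opposite strand, had 12.5 and 19.6 CPM against 0 and 0.406 CPM (log2 fold change −6.27, edgeR adjusted p = 0.999). Xist was counted in 82.9% and 94.0% of female cells and a Y-linked gene in 43.6% and 49.2% of male cells. In 2 male cells the sex-linked counts went against the label.

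No autosomal gene passed. Among 11832 autosomal genes, edgeR called 0, with 376 at an unadjusted p under 0.05, DESeq2 called 76 and limma-voom called 0. Splits that mixed the sexes also called 0 autosomal genes with edgeR. They had more at an unadjusted p under 0.05, 630 with 419 and 426 as a pair and 491 with 419 and 431 as a pair. None of the 10 autosomal genes with the smallest p that were expressed at the fixed level passed with edgeR. Their values did not overlap between the animals of the sexes, which a ranking by p favours. Ccdc80, a secreted matrix protein gene, had 0 CPM in both female animals and 48.1 and 26.2 CPM in the male animals (edgeR adjusted p = 0.217). Creg2 had 0 CPM in both female animals and 30.9 and 10.2 CPM in the male animals, and Klrk1, which encodes the receptor NKG2D, had 0.0969 and 0 against 26.6 and 6.61 CPM. Fgr, a Src-family kinase gene of myeloid cells, had 6.12 and 5.03 against 76.4 and 20.2 CPM, Lrrc8c had 0.985 and 0.329 against 18.6 and 20.1 CPM, and Zfp523 had 7.95 and 5.83 against 25.8 and 52.2 CPM. Values were higher in the female animals for Qpct, glutaminyl cyclase (64.2 and 69.1 against 9.84 and 12.6 CPM, log2 fold change −2.57, SE 0.46), Bysl (29.7 and 40.6 against 2.21 and 5.47 CPM), Secisbp2 (82.0 and 94.2 against 32.9 and 22.3 CPM) and Itpripl1 (114 and 183 against 56.7 and 41.8 CPM). Apart from Ccdc80, these had an edgeR adjusted p of 0.999. Of the X-linked genes known to escape inactivation, Kdm6a had 33.0 and 22.5 against 5.51 and 7.78 CPM (log2 fold change −2.06, SE 0.67) and Ddx3x had 111 and 109 against 38.4 and 72.2 CPM (−0.99, SE 0.41). Neither passed, nor did Kdm5c (−0.10), Eif2s3x (−0.31), 5530601H04Rik (−0.74) or 2610029G23Rik (0.95). Animals of the sexes did not overlap for 31.0% of all genes tested, where 1 in 3 is the share by chance. The count of called genes was 36 without female 419, 25 without female 421, 2 without male 426 and 4 without male 431.

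Genes of the MHC class II pathway, which presents peptides to CD4 T cells, were called as a list between the sexes. All 7 measured members had higher TMM-scaled values in both male animals than in both female animals. Their median log2 fold change was 0.95 (camera adjusted p = 3.9e-10, adjusted p = 0.831 with an estimated correlation, fry adjusted p = 0.913). H2-Aa had 912 and 562 CPM in the female and 1196 and 1675 CPM in the male animals (log2 fold change 0.96, SE 0.34), and H2-Ab1 had 1279 and 623 against 1792 and 2092 CPM (1.03, SE 0.38). Ciita, the transactivator of these genes, had 13.1 and 4.61 against 31.1 and 51.3 CPM (2.21, SE 0.71). The invariant chain gene Cd74 had 1405 and 687 against 1621 and 2430 CPM (0.95, SE 0.40). With library size as the only scaling, 5 of 7 members were higher in both male animals, because H2-Eb1 and Cd74 of male 426 then lay below those of female 419. None of the 7 genes passed over all genes or when adjusted over the list alone, and 3 had an unadjusted p under 0.05. The difference varied with the plates used, and a plate number marks a different plate in each animal. With plate 1 of each animal 7 of 7 genes were higher in both male animals (median log2 fold change 1.70). With plate 2 of each animal this held for 1 of 7, Ciita (median log2 fold change of the 7 genes 0.43). There 7 of 7 were higher in the fit (camera adjusted p = 0.00146). Male 426 had H2-Aa at 1235 CPM on its plate 1 and 792 CPM on its plate 2. Female 421 was low on its plate 1, with H2-Aa at 118 CPM there and 921 CPM on its plate 2 and Cd74 at 219 and 1074 CPM, and without that plate the median was 0.67 with 7 of 7 genes higher in both male animals (camera adjusted p = 1.8e-07). The values also rested on few cells, since without the 5% of cells highest in each animal H2-Aa went from 948 and 586 to 238 and 20.2 CPM in the female and from 1039 and 1771 to 328 and 1041 CPM in the male animals on library size. The median log2 fold change of female 421 against 419 was −1.22 (camera adjusted p = 1.7e-05 on plate sums), while the male animals differed by 0.55 (431 against 426, camera adjusted p = 0.195). The thinned share of cells with an H2-Aa count was 31.0% and 21.5% in the female and 39.0% and 53.1% in the male animals, and the median share of counts on the 7 genes was 0.0540% and 0.0350% against 0.0855% and 0.105% in thinned cells (0.0563% and 0.0364% against 0.0843% and 0.0999% unthinned).

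**Figure D1:**
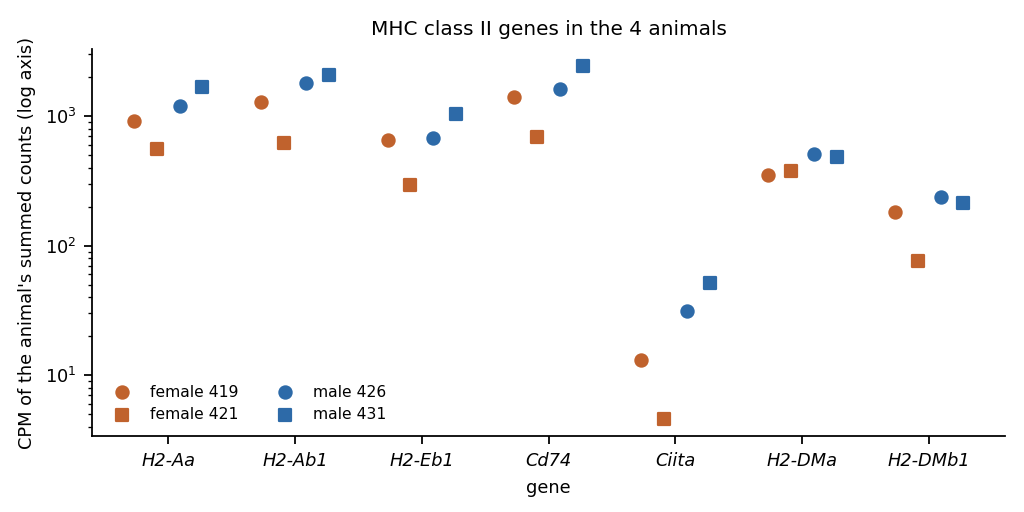
TMM-scaled CPM (log axis) of the 7 MHC class II genes, 1 point per animal, orange for female and blue for male animals. With both plates of each animal summed, both male points lie above both female points for 7 of 7 genes (5 of 7 on library size alone), with Ciita at 13.1 CPM in the higher female and 31.1 CPM in the lower male animal.

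The MHC class I genes shared this direction, with 11 of 12 measured members higher in the male mean (camera adjusted p = 0.000516, adjusted p = 0.831 with an estimated correlation). Among them H2-D1 had 1709 and 1342 CPM in the female and 2720 and 2340 CPM in the male animals (log2 fold change 0.73, SE 0.26), and Psmb8, an immunoproteasome subunit gene, had 217 and 150 against 279 and 280 CPM. The MHC class I list also differed between the female animals (421 against 419, median log2 fold change −0.54, camera adjusted p = 1.7e-05). Between the male animals it was 0.21 (431 against 426, camera adjusted p = 0.0938). Genes of disease-associated microglia (DAM), a programme of lipid handling and phagocytosis near pathology, were higher in the male mean for 25 of 26 members (median log2 fold change 0.80, camera adjusted p = 9.8e-06, adjusted p = 0.831 with an estimated correlation). The genes with the widest difference were high in male 426 alone. Gpnmb had 102 CPM there and at most 0.251 CPM elsewhere, Spp1 had 1173 CPM against 66.4, 41.2 and 7.35 CPM, and Ccl6 had 229 CPM against 41.4, 21.5 and 34.6 CPM. Timp2 and Ctsd were the 2 members higher in both male animals. Camera also called the ribosomal protein (76 of 77 higher in the male mean, adjusted p = 3.1e-06), lysosome and phagocytosis (19 of 20, adjusted p = 0.000359), oxidative phosphorylation (67 of 80, adjusted p = 0.00805), glycolysis (13 of 16, adjusted p = 0.00805) and Y-linked lists (4 of 4, adjusted p = 3.1e-06) as higher in the male animals, and the X escape list (1 of 6 higher, adjusted p = 0.0437) as lower. Each of these had an adjusted p of 0.831 with an estimated correlation. Examples were Rpl4 with 425 and 403 against 1022 and 464 CPM, Npc2 with 451 and 441 against 976 and 460 CPM, and Aldoa with 506 and 387 against 1179 and 427 CPM. The ribosomal, oxidative phosphorylation, glycolysis and lysosome lists were also lower in male 431 than in male 426. Their median log2 fold changes there were −0.79, −0.91, −1.14 and −0.29 (camera adjusted p = 8.7e-22, 9.3e-14, 4.2e-07 and 8.7e-05 on plate sums). By sex the medians were 0.41, 0.33, 0.55 and 0.28. Members higher in both male animals were 18 of 77, 14 of 80, 2 of 16 and 10 of 20. For every list except the Y-linked one, 0 genes passed when adjusted over the list alone. Without male 426, 5 lists were called, among them the MHC class II, MHC class I and Y-linked lists, and 6 of the 9 were no longer called.

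The microRNA machinery did not differ past the threshold (13 genes measured, 4 higher in the male mean, camera adjusted p = 0.143). Drosha, the nuclear enzyme that precedes Dicer, had 17.2 and 16.4 CPM in the female and 7.33 and 7.09 CPM in the male animals (log2 fold change −1.22, SE 0.80). The homeostatic microglia genes had a median log2 fold change of −0.04 (camera adjusted p = 0.407), with P2ry12 at 3028 and 4178 against 3303 and 3539 CPM. The other lists that were not called were the microRNA host gene, interferon response, inflammatory cytokine, immediate early, cell cycle, p53, complement, cholesterol, TGF-beta, border macrophage, monocyte, T and NK cell, dendritic cell, neuron, astrocyte and oligodendrocyte lists, 18 in all with camera adjusted p from 0.122 to 0.837. Of 16 immediate early genes marking dissociation 10 were higher in the male mean (median log2 fold change 0.23, camera adjusted p = 0.837), while the smallest p belonged to genes higher in the female animals, Nr4a1 at 37.0 and 9.36 against 0.217 and 1.24 CPM (log2 fold change −4.97, SE 1.34) and Dusp1 at 16.1 and 15.4 against 3.04 and 2.30 CPM (−2.56, SE 0.99), neither past the threshold (edgeR adjusted p = 0.999). The X inactivation, sex hormone receptor, mitochondrial transcript, neutrophil, B cell, endothelial and mural, and red cell lists had fewer than 3 measured genes and were not tested.

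Animals of the same sex also differed. In male 431 against male 426, edgeR called 10 genes on plate sums, with 1253 at an unadjusted p under 0.05. Lpl, lipoprotein lipase, was lower in 431 (log2 fold change −5.29, SE 0.52, edgeR adjusted p = 0.0232), as were Ccl3 (−5.01), Clec7a (−3.21), Gatm (−1.95), Cd63 (−1.75) and the ferritin genes Fth1 (−1.42) and Ftl1 (−1.52). Fut4 (13.72), Serinc3 (2.39) and H2-Ea-ps (10.52) were higher in 431. The DAM list had a median log2 fold change of −1.59 between these males (camera adjusted p = 6.9e-35, with no estimated correlation run between animals). In female 421 against female 419, Spint1 (−11.22, SE 0.75, edgeR adjusted p = 0.000778) and Lpl (−8.72, SE 0.71, edgeR adjusted p = 0.00237) were lower, and 481 genes had an unadjusted p under 0.05. These tests compare the named animals only. Between plate 2 and plate 1 of the same animals edgeR called 0 genes, with 383 at an unadjusted p under 0.05. Each animal had its own plates, so this test could call only a shift shared by all animals. It does not show that plates of an animal were alike. The common dispersion was 0.776 between plates of an animal and 0.736 between animals of a sex. The plate sums held 84 to 94 cells and the animal sums 172 to 183, so these values cannot be compared directly.

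The cells fell into 5 clusters. Cluster 1 (266 cells) was homeostatic-like, with Ecscr, Sall1 and Slc2a5 among its leading genes. Cluster 2 (248 cells) was led by Cyp4f18, Gdf3 and Klra2, with the border macrophage markers Pf4, Ms4a7 and Clec12a among its leading genes, and stayed unnamed. Cluster 3 (110 cells) was led by Spp1, Lpl, Cst7, Ccl3, Ccl6 and Clec7a, and 5 of its leading genes belong to the DAM list. Of these Cst7 was higher than in other cells in 4 of 4 animals, but Clec7a in 1 of 4 and Spp1 in 2 of 4, and its median of 889 detected genes was the lowest of the 5 clusters, with 91.2 counts per spike-in count against 236 in cluster 1, so it is referred to by number. Cluster 4 (71 cells) was led by Dnaic1, Emr4, Hsf2bp, Perp and Siglec5, and matched no marker list. Cluster 5 (16 cells) was interferon-responsive-like, with Ifit2, Ifit1, Ifit3 and Irf7 among its leading genes.

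Cluster 3 made up 41.3% of the cells of male 426 (71 of 172, exact 95% interval 33.8 to 49.0), against 13.7% of female 419 (8.99 to 19.7), 4.92% of female 421 (2.27 to 9.13) and 3.31% of male 431 (1.23 to 7.08). Cluster 1 made up 35.4% and 47.5% of the female and 22.1% and 43.6% of the male cells, cluster 2 35.4% and 41.0% against 22.7% and 39.8%, cluster 4 13.1% and 4.37% against 11.6% in male 426 and 20 of 181 cells in male 431, and cluster 5 2.29% and 2.19% against 2.33% and 2.21%. No difference in share by sex was shown. Exact permutation tests gave two-sided p from 0.667 to 1, and 2 animals against 2 cannot give less than 0.333. Among cells with at least 1500 detected genes, a limit set after seeing the data, cluster 3 held 25.3% in male 426 (16.7 to 35.5), 1.55% and 1.40% in female 419 and 421 and 0 of 138 cells in male 431 (upper bound of the exact interval 2.64%).

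**Figure D2:**
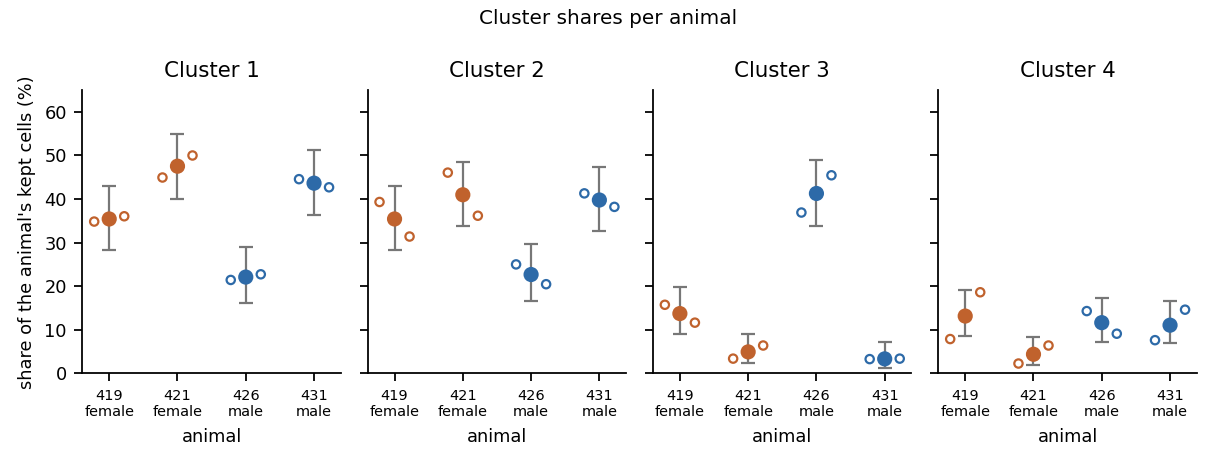
Share of each animal's kept cells (%) in clusters 1 to 4, orange for female and blue for male animals. Filled points are animals with exact 95% binomial intervals and open points their 2 plates, and cluster 3 stands at 41.3% in male 426 and at or below 13.7% in the other animals.

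Within cluster 1 alone, Xist was the only gene called between the sexes (10832 genes, edgeR, 369 at an unadjusted p under 0.05). Eif2s3y did not pass there. The MHC class II list was called in this cluster as well (camera adjusted p = 4.1e-08), as were the MHC class I (2.3e-06), DAM (2e-05), lysosome (0.000382), ribosomal protein (0.000732), inflammatory cytokine (0.0294) and Y-linked lists, and an estimated correlation was not run within the cluster. The count of called genes was 10 without female 419, 13 without female 421, 1 without male 426 and 8 without male 431. Tests of a different sex effect in cluster 2 or cluster 4 than in cluster 1 called 0 genes each with edgeR, with 232 and 138 genes at an unadjusted p under 0.05, and no other tool was used for them.

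Cells of cluster 2 had less of the homeostatic genes than those of cluster 1 when clusters were formed without any list gene. P2ry12, the ADP receptor of resting microglia, was at 5749 ± 710 CPM in cluster 1 and 1141 ± 369 CPM in cluster 2 (SD, n = 4 animals, log2 fold change −2.39, SE 0.19, edgeR adjusted p = 0.00247). Tmem119 was at 7477 ± 1305 and 3103 ± 463 CPM (−1.26, SE 0.11, edgeR adjusted p = 0.00303), and Sall1, a transcription factor of microglial identity, at 433 and 22.9 CPM (−4.39, SE 0.38). Of 18 homeostatic genes 13 were lower over all genes and 16 passed when adjusted over the list alone (camera adjusted p = 2.8e-44, adjusted p = 0.0720 with an estimated correlation), while Fcrls (0.00) and Mef2c (−0.08) did not pass. Apoe, the lipid carrier, was higher in cluster 2 in 4 of 4 animals (5551 ± 5419 to 54813 ± 7196 CPM, log2 fold change 3.79, SE 0.46, edgeR adjusted p = 0.0108), as was Axl (2.64, SE 0.47), while the DAM genes Cd9 (−1.63) and Ctsl (−1.93) were lower, so that the DAM list, with 4 of 25 genes past the threshold over all genes and 12 when adjusted over the list alone, was not called as a whole (camera adjusted p = 0.791).

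The MHC class II genes were higher in cluster 2 in 4 of 4 animals for 7 of 7 members (camera adjusted p = 2.5e-16, adjusted p = 0.144 with an estimated correlation). Of these H2-Ab1 (317 ± 251 to 3061 ± 1115 CPM, log2 fold change 3.73, SE 0.42) and H2-DMa (1.19, SE 0.20) passed over all genes with edgeR, and 7 passed when adjusted over the list alone. Interferon response genes were higher as a list (camera adjusted p = 1.9e-15, adjusted p = 0.144 with an estimated correlation), with 4 of 19 past the threshold over all genes and 16 when adjusted over the list alone, among them Ifitm3 (3.72, SE 0.40), Bst2 (2.60, SE 0.27) and Usp18 (3.59). The clustering without list genes did not separate the interferon-responsive-like cells, which lay mostly in this cluster. Border macrophage markers were higher too (camera adjusted p = 5.2e-09, adjusted p = 0.144 with an estimated correlation), with Ms4a7 at 7.92 ± 2.39 and 795 ± 82.3 CPM (6.70, SE 0.26) and Clec12a at 3.17 ± 3.50 and 186 ± 54.5 CPM (7.09, SE 1.16) past the threshold, and Mrc1 (4.23) and Pf4 (6.85) not. Across 433 list genes 36 were called by edgeR, 17 higher and 19 lower, and 11 of 25 lists were called and 14 not. The MHC class I (3.7e-08), ribosomal protein (3.9e-21), cell cycle (2.1e-05), monocyte (0.000216), inflammatory cytokine (0.00798) and cholesterol lists (0.0373) were higher by camera adjusted p and the complement list lower (0.000333), and none of the 11 passed with an estimated correlation. Cells were grouped by genes correlated with these lists, so the p-values overstate the separation. Leaving out female 419, female 421 or male 431 lowered the 36 list genes to 17, 20 and 22.

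**Figure D3:**
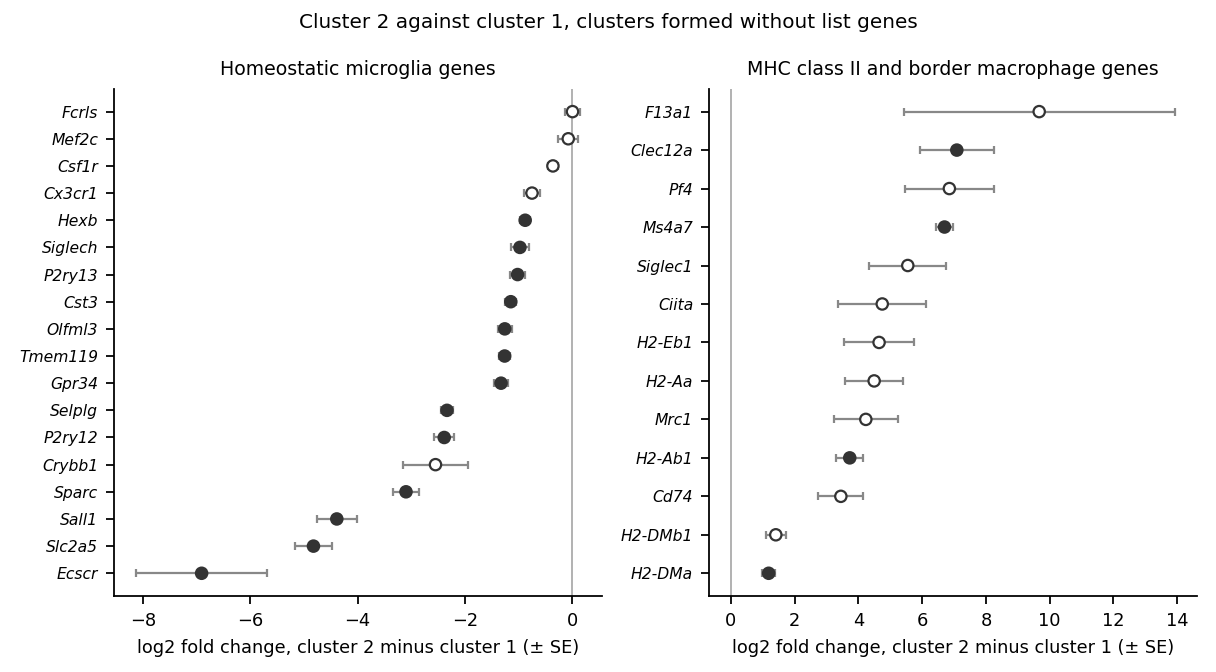
Log2 fold change (± SE, n = 4 animals) of cluster 2 minus cluster 1 for homeostatic genes on the left and MHC class II and border macrophage genes on the right. Filled points passed edgeR's adjusted threshold over all genes, as Sall1 at −4.39 and Ms4a7 at 6.70 did, and open points did not.

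Cluster 4 was compared with cluster 1 in the same way, with 22 and 7 cluster 4 cells in female 419 and 421 and 17 and 19 in male 426 and 431. Fcrls, a microglial Fc-receptor-like gene, was at 2515 ± 668 CPM in cluster 1 and 550 ± 66.1 CPM in cluster 4 (SD, n = 4 animals, log2 fold change −2.16, SE 0.24, edgeR adjusted p = 0.0324), and the lysosomal protease gene Ctsd at 21696 ± 6872 and 10368 ± 3627 CPM (−1.08, SE 0.11, edgeR adjusted p = 0.0312). These 2 of 388 list genes passed over all genes, and 11 homeostatic and 13 DAM genes passed when adjusted over the list alone. The homeostatic (camera adjusted p = 6.7e-05) and DAM lists (0.00013) were lower, each with an adjusted p of 0.673 with an estimated correlation, and 19 lists were not called. No list gene was called without female 421 or without male 426, and 1 was called without female 419. Of the lists 1 was called without female 419, 4 without female 421 and 1 without male 426. In the first clustering Apoe was at 68.5 and 82.2 CPM in the female and 2308 and 616 CPM in the male cells of cluster 4, against 3565 ± 1017 CPM in cluster 1 and 57244 ± 5574 CPM in cluster 2 (SD, n = 4 animals).

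From cell to cell, the homeostatic score fell as the MHC class II score rose in each animal (Spearman rho across cells −0.24 in female 419, −0.40 in female 421, −0.21 in male 426 and −0.34 in male 431). The homeostatic and interferon scores gave −0.32, −0.33, −0.07 and −0.34, and the interferon and MHC class II scores 0.27, 0.20, 0.18 and 0.37 (0.26, 0.12, 0.17 and 0.39 on unthinned counts). The DAM and homeostatic scores gave −0.08, −0.22, −0.08 and −0.11. A total of 28 pairs of scores were computed, and no p is given because cells are not replicates. Each correlation pooled the scored cells of all clusters of an animal. The cluster with border macrophage markers had lower homeostatic and higher MHC class II and interferon response levels, as given above. The correlations therefore cannot separate a difference between clusters from a relation among the cells of a cluster. Correlations within a cluster were not computed.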

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

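Tests with cells of at least 1500 genes, without cluster 2 or cluster 3, without Rn45s, without plate 1 of female 421 and all settings of the comparisons between clusters were chosen after the data were seen, and the others before. No paired analysis was possible because no animal number occurs in both sexes. Of 76 counts of calls under an alternative 44 stayed within 1.5 times and 32 did not. The 2 genes called between the sexes became 1 with library size only, on plate 1, on plate 2, with the mean over cells of log2(CPM + 10), without cluster 2 cells and without plate 1 of female 421. They became 0 with limma-voom and with 8 plate sums with the animal as a random block, 31 without a gene filter and 85 with DESeq2. Leaving out 1 animal gave 2 to 36, and the lone animal of a sex is then assumed to vary like the other sex. Counts within cluster 1 went from 1 to 13 in this way. The 9 lists called between the sexes became 0 with an estimated correlation and 1 with fry, the Y-linked list. For cluster 2 against 1, list genes ranged from 17 to 35 without 1 animal, and lists became 0 with an estimated correlation. For cluster 4 against 1, list genes became 4 with RLE normalization and 0 to 2 without 1 animal, and lists became 0 with an estimated correlation, 0 with fry and 1 to 4 without 1 animal. The cluster 5 share, male minus female, was −0.244 points at resolution 0.3, −0.262 on thinned counts and 0.549 in cells with at least 1500 genes, and 31 other shares moved by less than 1 SD. On unthinned counts 27 of 28 median score correlations moved by less than 1 SD and immediate early with cell cycle became 0.13. Of 570 fold changes of named genes 518 kept their direction and side of the threshold, 32 passed only in an alternative, 10 passed only in the reported setting and 10 reversed, none of them called. Dicer1 was −0.13 without cluster 3 cells and −0.26 in cells with at least 1500 genes. Kdm5c was 0.0246 on plate 1, 0.17 without cluster 2 and −0.31 to 0.0638 without 1 animal, above 0 without female 419 (0.0448) or male 426. Eif2s3x was 0.14 on plate 2 and −1.47 to 0.32 without 1 animal, above 0 without male 426. 2610029G23Rik was −0.0921 without cluster 3 and −0.53 to 1.64 without 1 animal, below 0 without male 426. The cause was not tested for any of these. Including other cell types was not run apart, because no cluster was named for another type. Simulated 2-fold changes were recovered in 0% of genes, so small autosomal differences were below what 2 animals against 2 can show.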

Other observations

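The tests of gene presence, of MHC class II levels, of cluster 3 and of the plates in cluster 4, and the site tests of cluster 4 against single clusters and against cells matched on detected genes, were chosen only after the result was seen. The site test of cluster 4 against all other cells and its correction for 3' UTR properties were set before.

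Several autosomal genes were present in 3 animals and nearly absent from 1 on both of its plates. H2-Ea-ps (chromosome 17, 34341952 to 34344645), a row of the class II region of the H2 complex that its symbol marks as a pseudogene, had 44.4, 259 and 124 CPM in female 419, female 421 and male 431 and 0.0687 in male 426. H2-Q4, a class I gene of the same complex, was counted in 125, 120 and 147 cells of those animals and in 5 cells of male 426. Fut4 on chromosome 9 was counted in 14, 6 and 14 cells of them and in 0 cells of male 426. Spint1, a protease inhibitor gene on chromosome 2, was counted in 34, 36 and 77 cells of female 419, male 426 and male 431 and in 3 cells of female 421, at 124, 127, 306 and 0.0490 CPM. Rras2 on chromosome 7 was near absent in female 421 as well (0.229 CPM in 3 cells, against 26.1, 21.1 and 19.3 CPM in only 9, 9 and 8 cells). The limits, at least 10 CPM on both plates against under 0.3, were set by looking at the data.

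Genes with 3' UTR sites for microRNAs of microglia were higher in cluster 4 than in other cells, as a hypothesis of lost repression in these cells would predict: across 14 families the mean site effect was 0.10 on the log2 scale, at percentile 100 of 1000 shuffled site sets (median 0.06), with 0.06 and 0.13 in female 419 and 421 and 0.15 and 0.13 in male 426 and 431. Of the 14 families 5 reached percentile 95 of their own controls (miR-21, miR-26 and miR-15/16 at 100, miR-142-3p at 96 and miR-29 at 95.3), while let-7 and miR-27 were at 40 and miR-23 and miR-125 at 28, and miR-9, a family of other tissues, was at 96. With UTR length, GC and expression in the regression the coefficient per family with a site was 0.0438 (SE 0.00955). No regression without these terms was run. The plate with the most cluster 4 cells held 22.5% of them. Against cells matched on detected genes (median 1973 in both sets) the percentile was 100. Across clusters the effect followed detected genes (0.04 in cluster 1 with 1845 genes and −0.16 in cluster 3 with 889 genes). Shuffled sites moved the same way (medians 0.04 and −0.12), so the trend does not depend on microRNA sites alone. Cluster 1 cells above their animal's median of detected genes were set against the rest (median 2064 against 1666 genes). Their site effect was −0.01, at percentile 17.5 (coefficient −0.0017, SE 0.0066). This split and the matched cells argue against more detected genes as the whole cause. The test is weak in several ways. Cluster 3 was at percentile 0, the 8 cells of female 421 at 93.3 and simulated data without an effect at 93.9. Sites of 4 families from other tissues were at 98.7 in cluster 2 and 99.7 between the sexes (25.4 in cluster 4). Genes are not independent, Dicer1 counts cannot mark recombined cells and no Dicer-intact cells were analysed here, so loss of microRNA repression in cluster 4 may explain the pattern but stays a hypothesis.

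Cluster 3 was most frequent in male 426, with 71 of its cells. Few detected genes as the whole cause is argued against by the cells with at least 1500 genes, of which 25.3% belonged to cluster 3 in male 426, with an interval above the highest upper bound of the other animals (5.49%). A fault of 1 plate is argued against by both plates, whose lowest lower bound, 26.6%, lay above the upper bounds of the other 6 plates. An event during the isolation of that animal and a difference in its disease stage stay open and were not tested, and a sex effect is not shown, since male 431 had the lowest share.

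MHC class II genes were higher in both male animals with the plates summed. With only plate 2 of each animal this held for Ciita alone, 1 of 7 genes (7 of 7 higher in the fit, camera adjusted p = 0.00146). Female 421 was low on its plate 1 (H2-Aa 118 against 921 CPM). Low values on that plate may contribute and stay open, because without it the median log2 fold change was 0.67 (median SE 0.32, 7 of 7 genes higher in both male animals, camera adjusted p = 1.8e-07) against 0.95 with it. Without the 5% of cells highest in each animal, 7 of 7 genes were higher in both male animals. With all cells on the same library-size scaling this held for 5 of 7. The levels then fell without those cells (H2-Aa to 238 and 20.2 CPM in female and 328 and 1041 CPM in male animals). A few cells with very high counts stay open as a cause of the summed levels, because a fixed 5% cut may leave further high cells. The median share of counts on the 7 genes in thinned cells does not depend on a few high cells. It was 0.0540% and 0.0350% in the female and 0.0855% and 0.105% in the male animals. Strain variants in the H2 region of chromosome 17 were neither supported nor excluded, since Cd74 and Ciita, which lie on other chromosomes, were higher on the male plate in 30 of 32 pairs of plates and the 5 H2 genes in 68 of 80, and H2-Ea-ps and H2-Q4 were near absent in male 426 but not in male 431. The library pool cannot be told apart from sex, as 0 of the sexes had animals in both pools, and sex itself stays open as well.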
